A study of Zea mays with 6 samples.

How the data were processed

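Laser-microdissected cortical cells of B73 maize primary roots, with or without ethylene, were profiled on 6 arrays of 2 colours. The dye labels put ethylene-treated RNA in Cy3 and untreated RNA in Cy5 on 3 arrays, and the reverse on 3 arrays described as colour swaps of the same replicate numbers. Per the labels' protocols, total RNA from the dissected cells was linearly amplified before labelling. Amplification of small amounts can add differences between RNA samples that repeated hybridisation does not average out.

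The spots were quantified with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. The deposited scanner files hold spot and background intensity for both channels, per the file headers without normalisation, and also processed intensities that the scanner software detrended, background-subtracted and dye-normalised. The authors' deposited value table holds log10 ratios: each column equalled the scanner's log10 ratio of Cy5 over Cy3 for its array within 5e-10, had a median of 0, and was not turned for dye swaps. Its scale and direction were thereby known, while whether any centring beyond the scanner's was intended is not given in the sources used here. Between 35.3% and 45.5% of its values were exactly 0, where both channels of a spot had been replaced by a surrogate. No genome build was given in the sources used here, and the files place all probes as unmapped, so no coordinates are printed.

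Each array had 43451 spots, of which 1417 were controls, and 42034 maize probes of 60 nt under 39174 feature names. No maize spot was saturated, and between 2 and 7 maize spots per array carried outlier flags and were left out. Mean spot and median background intensities were corrected with normexp (offset 50), and log2 ratios were normalised within each array by loess with control and flagged spots at weight 0, with limma 3.58.1 in R 4.3.3. The log2 ratio computed from the deposited intensities was turned to treated over untreated from the dye labels. The 2 arrays of a replicate are a technical repeat, so they were averaged, and n = 3. Averaging also cancels dye effects that are the same on both slides. Deviations from the mean of each dye orientation correlated between arrays of the same replicate with r from 0.774 to 0.874, which bears on the pairing given by the labels.

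Probes were tested if well above background, by the scanner's flag, on at least 4 of the 6 arrays in treated or in untreated RNA, which left 9914 and set aside 32120. The ratios were tested against 0 with limma (lmFit and eBayes, two-sided, prior degrees of freedom 2.12) and Benjamini-Hochberg adjustment at 0.05. The dye effect was taken from the 6 unaveraged ratios, with the replicate as a random block (consensus correlation 0.652). Where a probe was not well above background on any array of a group, the fold is a bound, from channel intensities after loess and Aquantile normalisation, with the dim side at the higher of its own signal and the lowest signal well above background on each array. Channel intensities printed for other probes come from the same step. The offset draws ratios of dim probes towards 0, so folds are understated.

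Background correction, normalisation and the fit were tested on simulated arrays with the mean intensities of the ethylene comparison (9914 probes fitted, 200 of them changed). The probes fitted were those that passed the filter on the real arrays, so the filter itself was not tested. Each probe's spread was drawn at random from the variance model of the fit, without a link to intensity, and probes varied independently. Of 50 probes changed by 1.41-fold, 3 passed; of 50 changed by 2-fold, 26; of 50 changed by 4-fold, 46; and of 50 changed by 8-fold, 48. The median estimates for log2 changes of 1 and 3 were 0.70 and 1.80. Among 132 simulated probes past the threshold, 9 (6.82%) were unchanged. These shares hold for arrays simulated in this way and need not carry over to the real ones. There, 22.3% of tested probes were at unadjusted p under 0.05 in limma, and 0 passed once an intensity trend was modelled.

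The features are named by identifiers of assembled transcripts or sequence accessions, with every description given as unknown. Only 2 names, AM1 and AI676903, on 4 probes, matched the reference table of gene symbols. The rule for named genes, fixed before the data were examined, called for up to 12 named genes in each direction past the threshold, with the same sign on all 6 arrays and well above background in the brighter channel throughout. No gene with a name met it, so the 2 probes with the largest rise and the 2 with the largest fall that met its other conditions were given, with features singled out afterwards said to be so. The 37 gene lists matched 0 features, and the set tests planned for them with camera and fry were not run.

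Spike-in signals were compared with the brightest 10% of tested maize probes (990 without flagged spots), whose log2 intensity of 9.17 or more overlaps that of the spike-in probes (9.75 to 15.7). The quantity is the difference between the dye orientations divided by 2, from intensities after normexp without loess. The labels do not say at which step the spike-in RNA was added. Alternatives fixed before the data were examined covered the scanner's processed signals, a normexp offset of 16, median centring, Aquantile, the deposited table, filters on dim probes, the variance model, arrays kept apart with or without a replicate block, each dye orientation, the slide, each replicate left out and the median over a feature's probes. The spike-in shift, each slide alone, the trend and the robust variance taken singly, and all alternatives for the dye effect were added after seeing the data. Slides and scan batches coincided: slide 1 held 4 arrays and slide 2 held 2, with treated and untreated RNA on every array. Opposite-strand probes were found with a shared stretch of at least 25 nt. Figures were drawn with matplotlib 3.10.9.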

Results

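RNA from cortical cells of the primary root of the maize inbred line B73 was compared between seedlings kept with and without 1 ppm ethylene for 6 h. Ethylene is a gaseous plant hormone, and in maize roots it can trigger the death of cortical cells that forms air spaces, called aerenchyma. The seedlings were 3 days old when the exposure began, and the cells were cut by laser microdissection from 16 µm sections of a root segment lying 15 to 20 mm from the junction of root and shoot. Treated and untreated RNA were labelled with different dyes and hybridised together on 6 arrays of 60-nt probes. The arrays made 3 replicates, each measured once with the treated RNA in Cy3 and once with the dyes exchanged, so n = 3 throughout. Of 42034 maize probes on each array, between 21.6% and 28.4% were well above background in the treated RNA and between 13.9% and 28.0% in the untreated RNA. The lowest share came from the untreated RNA of replicate 3 when labelled with Cy3. The number of arrays limits the precision of every value below. The labels number the replicates but do not say that they came from separate plants, so p-values measure only the spread between these RNA pairs, which may be technical.

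The comparison of treated with untreated RNA asks which transcripts of the cortex changed within hours of ethylene exposure. Of 9914 probes tested, 56 rose and 79 fell with ethylene (limma, Benjamini-Hochberg adjusted p under 0.05), and all 135 had the same sign on each of the 6 arrays. That agreement of sign follows largely from the selection, because a probe passes only if its mean is far from 0 for its spread. Most of these changes were estimated at under 4-fold. Of the probes that rose, 15 changed by under 2-fold, 33 by 2-fold to 4-fold and 8 by 4-fold or more. The corresponding numbers for the probes that fell were 25, 44 and 10. The median log2 ratio of treated to untreated RNA was 1.22 over the probes that rose and −1.24 over those that fell. The normexp offset draws ratios of dim probes towards 0, so these values understate their folds. With offset 16, 161 of 189 probes past the threshold changed by at least 2-fold, against 95 of 135 in the fit reported here. On the simulated arrays, log2 changes of 1 and 3 had median estimates of 0.70 and 1.80. The 2 probes with the largest rise and the 2 with the largest fall are named here by the array's own identifiers, because the files do not pair these with gene names and the reference table held none of them.

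Probe A_92_P028184, for the assembled transcript TC288876, rose most among the 56, with a log2 ratio of 3.62 ± 0.90 (SD, n = 3) and an adjusted p of 0.0477 in limma. This is a 12.3-fold difference between a normalised log2 intensity of 13.66 ± 1.11 in treated RNA and 10.04 ± 0.45 in untreated RNA, and the ratio lay between 2.52 and 4.61 on the 6 arrays. Its sequence is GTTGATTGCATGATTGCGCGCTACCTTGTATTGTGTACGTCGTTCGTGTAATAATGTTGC. Probe A_92_P005236, for TC283381, had a log2 ratio of 3.15 ± 0.68 (SD, n = 3; adjusted p = 0.0387, limma), an 8.86-fold rise, and the sequence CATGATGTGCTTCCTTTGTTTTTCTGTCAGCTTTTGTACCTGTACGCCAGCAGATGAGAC. Among the 79, the transcript that fell most was TC280517, whose probe A_92_P011421 had a log2 ratio of −3.59 ± 0.79 (SD, n = 3; adjusted p = 0.0387, limma). Its normalised log2 intensity was 8.92 ± 1.08 in treated and 12.51 ± 0.31 in untreated RNA, a 12.1-fold fall, and its sequence is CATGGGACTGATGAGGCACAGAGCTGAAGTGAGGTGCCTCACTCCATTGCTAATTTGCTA. For TC302489, probe A_92_P020330 gave −2.94 ± 0.69 (SD, n = 3; adjusted p = 0.0443, limma), a 7.68-fold fall, with the sequence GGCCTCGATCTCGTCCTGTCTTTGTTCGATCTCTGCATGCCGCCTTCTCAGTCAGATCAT. All 4 probes were well above background in both channels of all 6 arrays. Over the alternative settings, the log2 ratio ranged from 3.23 to 4.28 for TC288876 and from 2.77 to 3.64 for TC283381. It ranged from −4.04 to −3.1 for TC280517 and from −3.63 to −2.45 for TC302489. Of 22 other settings fitted by probe, the call of TC288876 held in 12, and those of TC283381, TC280517 and TC302489 in 14 each. The settings counted here and below include fits with the arrays of a replicate kept apart, which count technical repeats as samples. They also include Aquantile, which left the ratios unchanged, so these tallies overstate how stable the calls were.

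**Figure D1:**
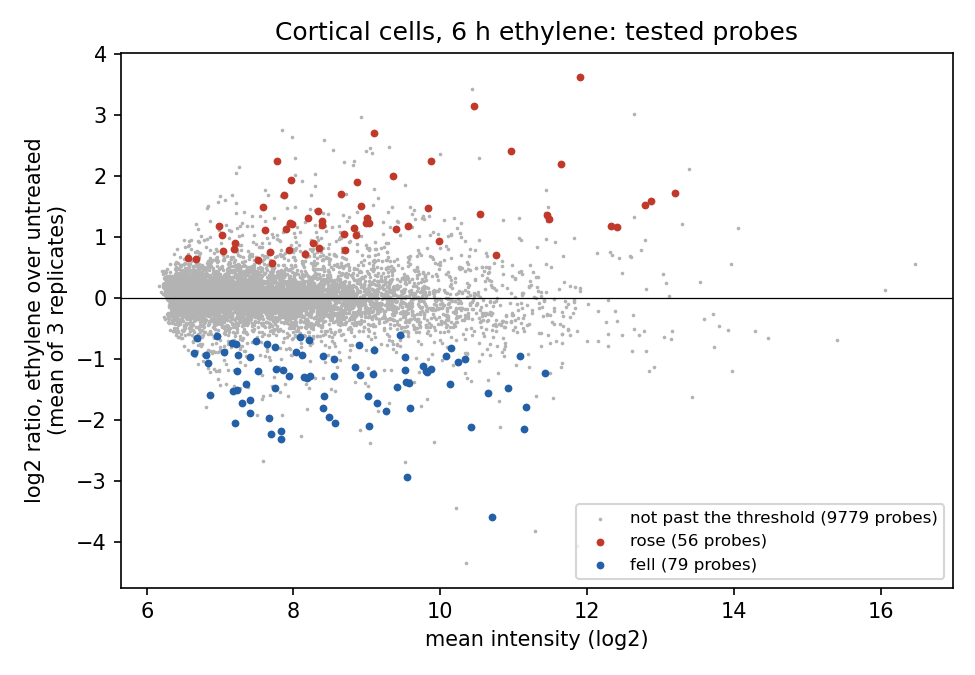
Log2 ratio of ethylene-treated to untreated RNA (vertical axis, mean of 3 replicates) against mean log2 intensity (horizontal axis) for the 9914 tested probes, each point a probe. The 56 probes that rose and the 79 that fell lie across the intensity range, and the extremes among them are 3.62 and −3.59.

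Features represented by several tested probes gave a check within the array. Of 175 such features, 3 had a probe past the threshold, and within each of these both probes had the same sign. They were chosen after their values were seen. TC300557 rose on both of its probes, with log2 ratios of 2.26 ± 0.47 and 2.00 ± 0.39 (SD, n = 3), each with an adjusted p of 0.0387 in limma. TC282722 fell on both, with −1.72 ± 0.16 and −1.06 ± 0.11 (SD, n = 3; adjusted p = 0.0277 and 0.0315, limma). TC280488 had −0.82 ± 0.02 on a probe past the threshold (adjusted p = 0.0323, limma) and −0.74 ± 0.13 on another that was not (adjusted p = 0.0514), each over n = 3. Other settings moved the values of TC282722 and TC280488 by over 1.5 times. Those of TC282722 became −3.64 and −3.01 with the scanner's processed signals (adjusted p = 0.0509 and 0.0499, limma), and −1.22 and −0.57 (0.18 and 0.487) once moved by the shift relative to spike-in probes. The probe of TC280488 past the threshold became −0.42 (adjusted p = 0.461, limma) with median centring and −0.32 (0.562) with the spike-in shift, and its other probe became −0.28 (0.575) and −0.24 (0.652). That other probe passed in 8 of 22 settings fitted by probe. Both probes of TC300557 lost the call in 8 settings although their ratios did not shrink. They were 2.57 and 2.36 with the processed signals (adjusted p = 0.0561 and 0.0514, limma) and 2.63 and 2.41 with the deposited table (0.0618 and 0.0585). Median centring gave 2.7 and 2.45 (0.0732 each). The other losses came with an intensity trend, alone or with robust variance, without replicate 1, without replicate 2 and on slide 2 alone. Each probe of TC300557 passed in 14 of 22 settings. Across all 175 features, the ratios of the first 2 probes had the same sign in 145 cases (82.9%) and a correlation of 0.642 across features, which are not independent replicates.

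In 2 of the 135 probes, again picked out after their values were seen, the treated RNA was not well above background on any array. For these the change is a bound. The transcript CO525399 (probe A_92_P037986) was at least 2.85-fold lower in treated RNA and TC279812 (probe A_92_P019844) at least 1.84-fold lower, each with an adjusted p of 0.0315 in limma. The bounds hold for the loess-normalised signals only, and the fitted log2 ratios, which do not measure the size of these changes, depended on the setting. They were −0.90 for TC279812 and −1.59 for CO525399, became −3.70 and −5.11 with the scanner's processed signals (adjusted p = 0.0478 each, limma), and became −0.40 and −1.10 with the spike-in shift, where both lost the call (0.501 and 0.285).

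**Figure D2:**
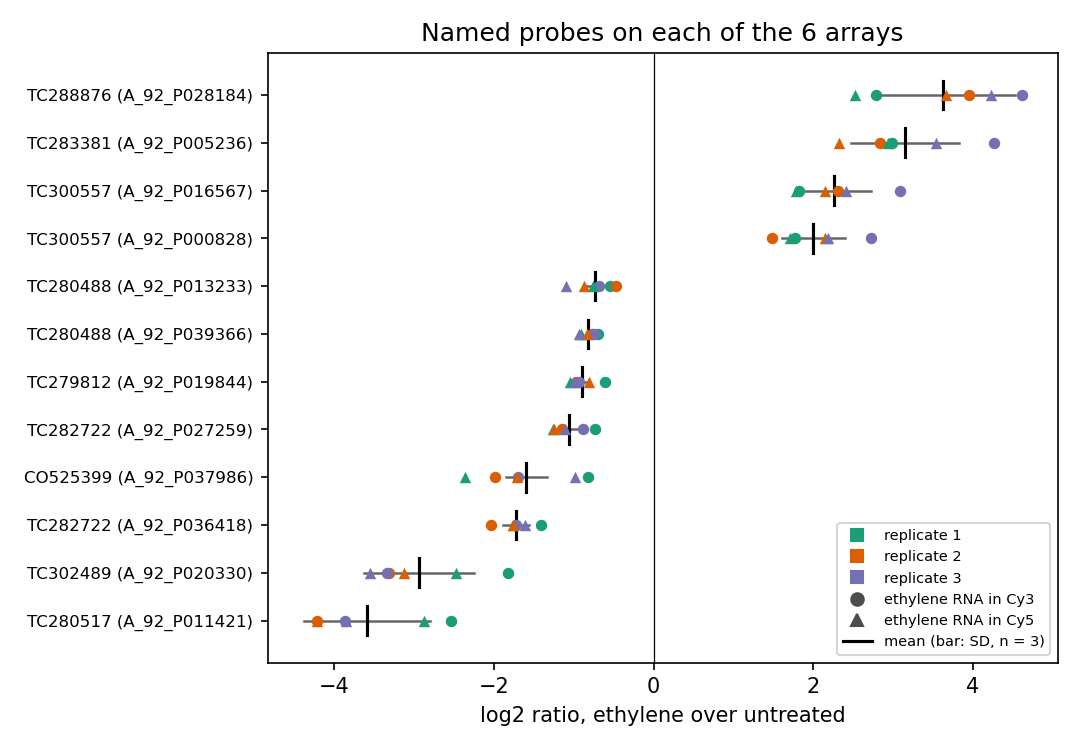
Log2 ratio of ethylene-treated to untreated RNA (horizontal axis) of the 12 probes described by identifier, 1 per line. Symbols are the 6 arrays, coloured by replicate and shaped by dye orientation, with the mean as a vertical tick and its SD over 3 replicates as a grey line. Every array lies on the same side of 0 as its probe's mean, which the choice of the probes largely implies. The arrays range from −4.21 to −2.53 for TC280517 and from 2.52 to 4.61 for TC288876.

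The array gives gene names for 22 probes only, and 20 of them were not well above background on any array in either channel. These were all 7 probes for ZmRAD21 and both for ZmSMC1, which encode cohesin subunits, 3 of the 4 for ZmSMC3, another cohesin subunit, the single probe for ZmSGO1, a protector of centromeric cohesion, all 3 for AM1, a regulator of the entry into meiosis, and the 4 for the transposon MuDR. The remaining probe for ZmSMC3 had a log2 ratio of 0.06 ± 0.09 (SD, n = 3; adjusted p = 0.653, limma). For ZMATP70 the log2 ratio was −0.13 ± 0.24 (SD, n = 3; adjusted p = 0.541, limma). Another measured gene, AI676903, is LOC100279569 in the reference table for assembly Zm-B73-REFERENCE-NAM-5.0, and had 0.04 ± 0.12 (SD, n = 3; adjusted p = 0.777, limma). None of these 3 passed the threshold, and the sign of each turned under at least 1 other setting.

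Of the 37 gene lists fixed beforehand, including those for ethylene synthesis and signalling, cell wall loosening, reactive oxygen, calcium and the markers of neighbouring root tissues, 0 matched any feature name, so no gene group could be tested. By origin of the sequence, 119 of 8894 tested probes for assembled transcripts passed the threshold (47 rose, 72 fell), against 16 of 984 for single sequences or named genes (9 rose, 7 fell). No difference between the shares of 1.34% and 1.63% was detected by Fisher's exact test (two-sided p = 0.468).

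The number of probes past the threshold depended on how the spread was estimated and on the replicates used. With the 6 arrays kept apart, a dye term and the replicate as a block, 1087 probes passed (568 rose, 519 fell), whereas 0 passed in limma with an intensity trend and robust variance (2057 at unadjusted p under 0.05), without replicate 1 (1561) or without replicate 2 (1401). In the fit reported here, 2211 probes (22.3%) were at unadjusted p under 0.05 in limma, where 5% are expected without any change, and 95 of the 135 changed by at least 2-fold. The balance of directions was not stable either: 106 rose and 68 fell without replicate 3, 5 rose and 20 fell with median centring in place of loess, and 187 rose and 22 fell once ratios were moved by the shift of maize signal relative to the spike-in probes. The last setting adds the same shift to every probe of a replicate and moved the median of all tested probes to 0.51, from 0.01, so more rises follow from its construction. Within slide 1, which held both arrays of replicate 1 but only those with treated RNA in Cy5 of replicates 2 and 3, 175 probes passed, and with the slide as a random block 3172 passed. Slide 2 held only 2 arrays, from replicates 2 and 3 and both with treated RNA in Cy3, and 0 probes passed in limma (1545 at unadjusted p under 0.05). The dye effect is not fully cancelled on either slide.

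Replicates differed from each other more than the arrays of a replicate did. Across tested probes, the ratios of arrays of the same replicate correlated with r between 0.787 and 0.876, and those of arrays from different replicates between 0.376 and 0.66. After averaging, replicates 1 and 2 had r = 0.671, replicates 1 and 3 had 0.508, and replicates 2 and 3 had 0.527, all across probes, which are not independent replicates. Relative to 10 spike-in control probes, bright maize probes had log2 ratios of treated to untreated signal of −0.24 ± 0.02 in replicate 1, 0.52 ± 0.08 in replicate 2 and 1.19 ± 0.08 in replicate 3 (SD over the spike-in probes). A dye effect passed the threshold for 354 of the 9914 tested probes (184 brighter in Cy5, 170 in Cy3; limma), with a median size of 0.23 on the log2 scale. In replicates 2 and 3 the dye orientations also differed in slide, so this effect may include a slide effect. Among the 135 probes, 13 carried it, a larger share than among all tested probes. The difference in share was not tested.

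**Figure D3:**
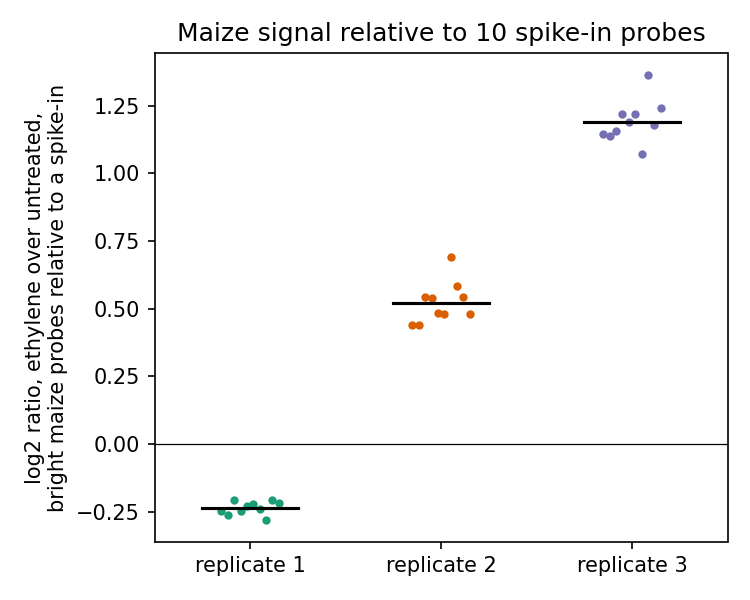
Log2 ratio of ethylene-treated to untreated signal of bright maize probes relative to each of 10 spike-in probes (vertical axis, 1 point per spike-in probe), by replicate, with the mean as a black line. The means are −0.24, 0.52 and 1.19 in replicates 1 to 3.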

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

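Apart from the dye effect, which was planned, the tests in this part were chosen after the results they concern were seen. The ratio of treated to untreated RNA differed between the dye orientations for 354 probes (limma, with the replicate as a block), which was tested as a dye term. A dye effect that is the same on both slides is cancelled in the averaged ratios. For replicates 2 and 3, the orientations were on different slides, which were scanned apart. A dye effect cannot be told from a slide effect there, and a slide effect need not cancel.

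The spike-in probes, which no comparison of the report uses for its calls, carried a signal of their own. In replicate 3, bright maize probes had a treated over untreated log2 ratio of 1.19 ± 0.08 (SD over 10 spike-in probes) relative to them, a 2.29-fold difference, against −0.24 ± 0.02 and 0.52 ± 0.08 in replicates 1 and 2. A dye or scanner difference is argued against: the Cy5 over Cy3 shift of replicate 3 from the other replicates was −1.07 with treated RNA in Cy3 and 1.06 with treated RNA in Cy5, so it followed the RNA. Less maize RNA relative to spike-in RNA in the untreated sample of replicate 3 may account for it. Probes well above background were 8.32 percentage points more frequent in treated than in untreated RNA there, against at most 2.07 in the other replicates. That gap shows a weaker maize signal in the untreated RNA, which is part of the observation, and cannot tell what weakened it. A change of total maize RNA with ethylene, the biological explanation, cannot be decided from these values. The RNA was amplified and the step at which spike-in RNA was added is not given, so the ratio need not report RNA per cell. The 3 replicates, with a mean of 0.49 ± 0.71 (SD), are also few, and replicate 1 went the other way. The size depends on the probes and normalisation. Over all tested probes without loess the replicates gave −0.16, 0.25 and 0.34, where replicate 3 lay close to replicate 2, and after loess −0.39, 0.80 and 2.48. The offset draws dim ratios towards 0: without loess, the median ratio of replicate 3 was 1.59 over bright probes and 0.35 over the dimmest 25%. The closeness over all probes therefore does not show that replicates 2 and 3 were alike. The cause of the shift was not tested.

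Replicate 3 also correlated less with replicates 1 and 2 (r = 0.508 and 0.527 across tested probes) than these did with each other (0.671). Noise of single hybridisations is argued against, because the arrays of replicate 3 correlated with r = 0.87, above the highest value between arrays of different replicates, 0.66. Probes near the background may contribute: the gap in r was 0.091 among the brightest 25% of tested probes (2479) and 0.053 among those detected in both channels of all arrays (5445), against 0.145 over all, so it shrank without closing, and the share they account for cannot be told. No biological explanation was tested.

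For the 135 probes past the threshold, exchanging the treated and untreated labels within replicates makes only 4 patterns, too few for a share under 0.05; 1 of the 4, the real one, gave as many, and the highest of the others gave 0 (limma; between 88 and 276 at unadjusted p under 0.05). A change of at least 2-fold the same way in all 3 replicates was seen for 121 probes (54 up, 67 down) and, under the other patterns, for 1, 3 and 5. The ratios of the replicates correlate positively, so turning 1 of them lowers both counts whatever the replicates share. The contrast shows agreement between replicates and cannot tell where it comes from. A trend with the GC content of the probes is argued against as the source of the calls, because it reached at most 0.0482 on the log2 scale in any replicate, and the smallest change past the threshold was 0.58. Subtracting so small a trend still changed the count to 193, so many probes lie close to the threshold.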

How the results depend on the processing

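The alternatives using the spike-in shift, single slides, the trend or robust variance alone, and those for the dye effect were chosen after seeing the data. Against 135 probes past the threshold (56 rose, 79 fell), the cause of each difference was not tested unless stated. The scanner's processed signals gave 17 (6 and 11), the deposited log10 ratios 19 (7 and 12) and median centring 25 (5 and 20), where 9, 11 and 20 of the 135 passed. Without a filter on dim probes 324 passed (147 and 177), and all 135 were among them. With both channels detected on all arrays 191 passed (87 and 104). Keeping the 6 arrays apart counts repeats as samples in part or in full: 1087 (568 and 519) passed with the replicate as a random block, 5008 (2676 and 2332) with it as a fixed block, where only the spread between paired arrays is tested against, 2030 (1092 and 938) with arrays as independent, and 3172 (1708 and 1464) with the slide as a block. Arrays with treated RNA in Cy5 gave 377 (212 and 165). Slide 1 alone gave 175 (90 and 85). Leaving out 1 replicate gave between 0 and 174 (0 to 106 rose, 0 to 68 fell): 0 without replicate 1 or 2, with fewer samples, and 174 without replicate 3. Of the 135, only 78 were among those 174. In limma, 0 passed (0 rose, 0 fell) with an intensity trend and robust variance (lowest adjusted p 0.234; 2057 at unadjusted p under 0.05), with the trend alone (0.085; 2327) or on slide 2 alone (0.0596; 1545), which has 2 replicates in 1 dye orientation. Moving the ratios by the spike-in shift gave 209 (187 and 22), with only 52 of the 135 among them, and moved the median of all tested probes to 0.51 on the log2 scale, from 0.01. The other alternatives (offset 16, Aquantile, treated RNA in Cy3, robust variance alone, the median over a feature's probes) stayed within 1.5 times. Of the 135, 125 passed with offset 16, 113 with treated RNA in Cy3 and 103 with robust variance alone, so similar counts need not mean the same probes.

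The dye effect, 354 probes, became 7404 with median centring, 790 with both channels detected, 614 with processed signals and 0 in limma without a filter.

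The 11 probes past the threshold named by identifier passed in 159 of 249 alternative values. This count includes the fits that take repeats as samples, and Aquantile, which left the ratios unchanged, so it overstates stability. The direction of the 11 probes is no measure of stability either, since passing the threshold largely implies 1 sign on all arrays. Those with the largest rises and falls were also chosen for it. Their adjusted p in limma reached 0.949 for TC288876 and 0.667 for TC280517 with the intensity trend alone. That setting changes the variance model only, and the log2 ratios stayed at 3.62 and −3.59. Signs turned for the named genes that were not past the threshold, the cause not tested. ZMATP70 passed with the fixed replicate block (−0.13, adjusted p 0.0324), and became 0.36 with the spike-in shift and 0.0192 on slide 2. AI676903 became −0.22 with median centring, −0.0467 with treated RNA in Cy3, −0.0261 without replicate 1 and −0.0785 on slide 2. ZmSMC3 became −0.0745, −0.0375 and −0.14 with median centring, treated RNA in Cy3 and slide 2.

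Signal over background limits the array to 9914 of 42034 probes, and 5445 in both channels of all arrays.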

Other observations

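The array holds 550 pairs of probes of opposite strands that share at least 25 nt, so that each member reads the transcript of the other strand. In 198 pairs 1 probe was detected well enough to be tested, in 348 neither was, and in 4 both were. With 18.7% of the 1100 probes in such pairs tested, 19.3 pairs would hold 2 tested probes if the strands were detected independently. Of the 135 probes past the threshold, 6 belonged to such pairs (2 rose, 4 fell), each with an opposite-strand probe that was not tested. The pairs held 206 tested probes, and 1.36% of all tested probes passed. The difference in share was not tested, and the count is small. Of the 4 pairs with both strands tested, 3 had ratios of the same sign, and none of their probes passed the threshold in limma.

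Detection differed by the origin of the sequence. Probes for assembled transcripts were tested in 32.7% of cases (8894 of 27161), those for single sequences or named genes in 6.85% (984 of 14358), those for annotated coding sequences in 7.27% (12 of 165) and those for genomic assemblies in 6.86% (24 of 350). In the last 2 classes 0 probes passed the threshold in limma, with few tested.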
